A study of Mus musculus with 6 samples.

How the data were processed

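Retinal RNA from 3 wild-type and 3 Vldlr knockout mouse samples was hybridised to Illumina mouse BeadChips with 1 colour, 1 array per sample. Per the labels' protocols, total RNA was extracted with the RNeasy Mini Kit (Qiagen) and biotin-labelled cRNA was made with the Ambion Illumina TotalPrep kit. The labels give the same background strain entry (JAX) for both groups. It names no strain, so a shared strain cannot be taken as given. Per the submitters' processing notes the arrays were read out with GenomeStudio, whose version is not given in the sources used here. Groups were taken from the source names in the labels, and replicate numbers follow the order of the samples within a group and only name them.

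The authors deposited a non-normalized table of probe intensities on a linear scale, with a detection p-value per probe and array, per the file headers. They deposited a further table named as normalized and a value table of the whole series. Compared probe by probe, the normalized intensities equal the non-normalized ones minus 1 constant per array (57.2 to 69.1, largest deviation 0.1), with no scaling between arrays, and the value table of the series differs from it in 0 values. The detection p-values of both tables differ in 0 values. The median of the background-subtracted intensities lay between 6.3 and 8.4 per array, and between 11841 and 13093 of the 45281 values per array were below 0. All columns of per-sample values were used.

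The non-normalized intensities were background-corrected and normalized with neqc of limma (version 3.58.1 in R 4.3.3), which fits normexp with negative controls inferred from the detection p-values, adds an offset of 16, quantile-normalizes and takes log2. A probe was tested if its detection p was under 0.05 on at least 3 of 6 arrays, which left 19921 probes. Gene symbols came from the platform's annotation, in which 34885 probes had 1 symbol, 18 several and 10378 none. The entrez identifiers of 34807 of them matched the reference gene table (assembly GRCm38.p6), and 0 symbols changed. No coordinates of that assembly are given here, and it was used for names and for which genes neighbour each other. Probes with several symbols or none were tested as unnamed features. A gene with more than 1 tested probe (4146 genes) was represented by the probe with the highest mean log2 signal, and disagreement between probes is reported for named genes. This gave 13989 features. The number of arrays limits the precision, and with quantile normalization and a background offset, changes of dim probes are compressed towards 0.

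Knockout and wild-type arrays were compared by limma (lmFit and eBayes, 2-sided, group as the only term) with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Error is given as the SD between arrays of a group or the moderated SE of the difference. Where a probe was above background on 0 arrays of a group, its change is given as a lower bound. Before the data were examined, 35 gene lists were fixed from general knowledge of retinal cell types, tissues next to the retina and metabolic, vascular and stress pathways, and 34 of them had at least 5 tested genes. The list of free fatty acid receptors had 2 tested genes (Ffar3 at -0.35 and Gpr84 at -0.10) and was not tested. Lists share some genes. Each list was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over all lists. Counts of members are given over all genes and adjusted over the list alone.

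Genes named in the text were chosen by a rule fixed before the data were examined. It takes Vldlr, then the 12 largest increases and 12 largest decreases among named genes past the threshold whose groups do not overlap, up to 4 members of each list with the smallest p, and a fixed set of genes, of which Vegfa, Slc2a1, Ffar1, Gfap, Opn1sw, Opn1mw and Lrp8 are reported here. Predicted genes without a usual symbol were passed over.

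The fit was tested on simulated data made from these arrays, with 19782 probes tested. Noise was drawn for each probe on its own, so false calls from variation shared between probes were not measured. A change of 0.5, 1, 2 and 3 on the log2 scale was called in 2%, 26%, 90% and 86% of the 50 changed probes of each size, and 4 of 106 calls were false. The alternatives tried were other normalizations (quantile normalization of raw signal, median scaling, the authors' tables with values under 16 set to 16), an offset of 50, no filter or a strict filter (detection p under 0.01 on all arrays of a group), the mean of a gene's probes or every probe on its own, a trended and robust variance, array weights, thresholds of 1.5-fold or an adjusted p of 0.10, leaving out each array, the number in the sample title as a block, leaving out genes within 10 Mb of Vldlr, and, chosen after seeing the data, leaving out knockout replicate 1 and wild-type replicate 3 together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.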

Results

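RNA from mouse retina was measured on Illumina BeadChip arrays, with 1 array for each of 3 wild-type samples and 3 samples from Vldlr knockout mice. Vldlr encodes the very low density lipoprotein receptor, which takes up triglyceride-rich lipoprotein particles and is also a receptor for reelin. The comparison asks which retinal transcripts differ when the receptor gene is disrupted. The labels name no strain, so a strain difference between the groups could enter the same comparison. Each array carried 45281 probes, of which between 18710 and 20974 per array (41.3% to 46.3%) had a detection p under 0.05. The median raw signal lay between 63.9 and 75.9 in all arrays. Precision is limited by the number of arrays, 3 per group. Nothing in the labels says that the samples of a group came from separate animals, so all p-values measure only the spread between these samples, which may be technical.

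The first principal component held 43.9% of the variance and parted the groups, with the wild-type arrays between -43.9 and -5.37 and the knockout arrays between 19.6 and 29. Across probes, which are not independent replicates, the knockout arrays correlated more closely with one another (median r of 0.983 to 0.989) than the wild-type arrays did (0.9664 to 0.9752). Wild-type replicate 3 had the lowest of these values, and wild-type replicate 1 correlated slightly more with the knockout arrays (median r of 0.9787) than with its own group (0.9747). Knockout replicate 1 had the highest lens transcripts, with a median log2 level of 10.52 over the lens list against 5.07 to 7.77 in the other arrays.

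Vldlr mRNA itself was lower in the knockout retinas. On the brightest of its 6 probes the log2 signal was 11.43 ± 0.208 (SD, n = 3) in wild-type and 10.26 ± 0.129 (SD, n = 3) in knockout arrays. It fell by 1.18 on the log2 scale (SE 0.176, limma adjusted p = 0.0074), which left 44.3% of the wild-type signal. The next brightest probes fell by 1.23 and 1.26, to 42.7% and 41.8% of wild-type, with adjusted p = 0.0329 and 0.026 over all tested probes. All 3 of these probes stayed above background on all 6 arrays, and every knockout array lay below every wild-type array. The remaining probes were dim: 2 differed by 0.23 and 0.02 (adjusted p = 0.857 and 0.992), and the last was detected on 0 arrays. Where the probes lie relative to the disrupted part of the gene is not known here, and a probe outside that part does not check the genotype. Without knockout replicate 1 the Vldlr change was -1.12 (adjusted p = 0.0535) and without knockout replicate 2 it was -1.15 (adjusted p = 0.0563), so that the call was lost in both. Over all 19 alternatives its adjusted p ran from 0.000455 to 0.223.

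**Figure D1:**
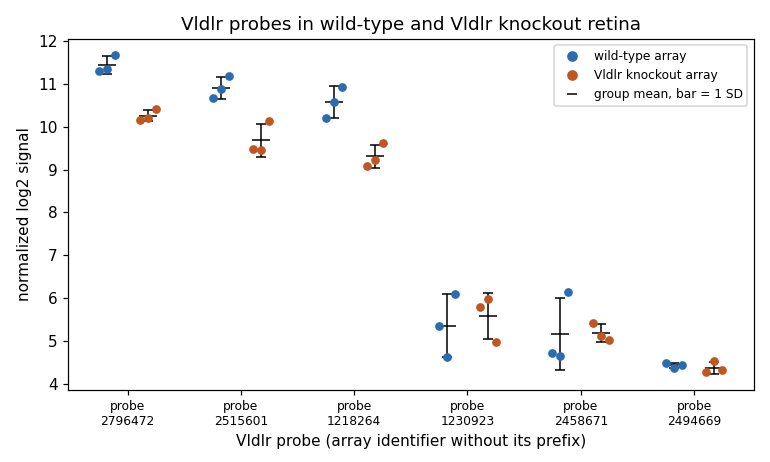
Normalized log2 signal (vertical axis) of each of the 6 Vldlr probes (horizontal axis) in the 3 wild-type and 3 knockout arrays; points are arrays, horizontal marks are group means and bars are 1 SD. On the 3 bright probes, which fell by 1.18, 1.23 and 1.26, every knockout array lies below every wild-type array, while the 3 dim probes overlap between groups.

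Of 13989 features tested (11089 named genes and 2900 probes with no gene name here), 350 passed an adjusted p of 0.05 by limma. The knockout retinas had 106 of them higher and 244 lower. Among named genes, 83 rose and 197 fell. Large changes were mostly decreases: by fitted values, 10 features were at least 4-fold higher and 68 at least 4-fold lower. For features not above background in 1 group only a lower bound holds, which can lie under 4-fold. In 59 of the features that fell, the signal was not above background on any knockout array, and in 9 that rose it was not above background on any wild-type array. The groups did not overlap in all 350, and in 2602 (18.6%) of the features tested, where chance gives 10%. At an unadjusted p under 0.05 there were 1733 features by limma, against 699 by chance. Both chance values are averages. Other splits of these arrays into 3 and 3 gave 104 to 1329 features at that threshold. Each of those splits mixes the groups, so a group difference enters its spread and its contrast. How far a chance count spreads around 699 is therefore not known here. The count of 350 was 156 without wild-type replicate 2, and 208, 176 and 233 without knockout replicates 1, 2 and 3. It was 170 with the authors' table (28.2% of them higher) and 960 with array weights (43.9%), against 30.3% of the 350. The number that rose was 66, 46, 42, 29 and 64 without wild-type replicate 1, wild-type replicate 2, knockout replicate 1, knockout replicate 2 and knockout replicate 3, respectively.

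**Figure D2:**
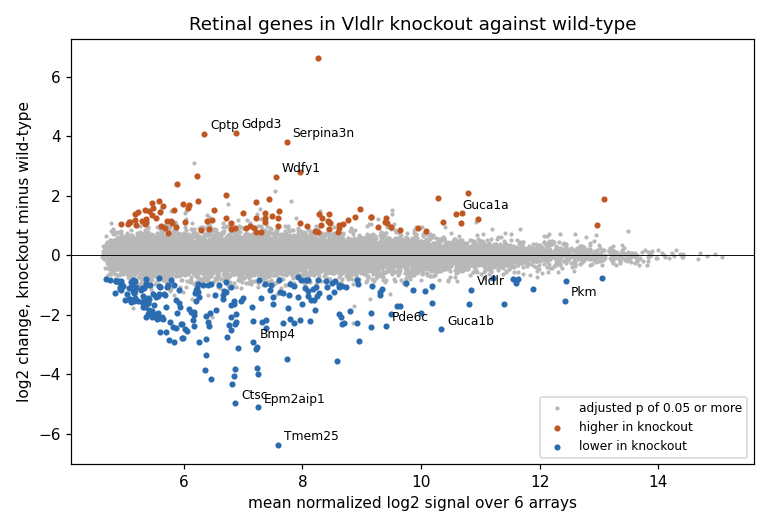
Difference in log2 signal between knockout and wild-type retina (vertical axis) against the mean log2 signal over 6 arrays (horizontal axis) for each of the 13989 features tested. Coloured points are the 106 features that rose and the 244 that fell at an adjusted p under 0.05, with some named genes marked.

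The largest increases among named genes were in Gdpd3, Cptp and Serpina3n. Gdpd3, a phospholipase of the glycerophosphodiesterase family, rose by 4.12 on the log2 scale (SE 0.242, adjusted p = 2.87e-05). Its probe was detected on 1 of 3 wild-type arrays. Serpina3n, a secreted serine protease inhibitor induced in reactive glia, rose from 5.83 ± 0.594 (SD, n = 3) to 9.64 ± 0.121 (SD, n = 3), a change of 3.81 (SE 0.277, adjusted p = 0.000133). Wdfy1, an endosomal protein, rose by 2.64, and Masp2, a protease of the lectin pathway of complement, by 2.40, with its other probe higher too. The cytokine Il18 rose by 1.87 (SE 0.213, adjusted p = 0.00144), the lysosomal protease Ctsl by 1.83 and the potassium channel subunit Kcnj9 by 1.75. The probes of Masp2, Ctsl and Kcnj9 were each detected on 1 of 3 wild-type arrays, so the size of these rises is limited by background. For several increases the gene had another probe that moved less or the other way. Cptp, a ceramide-1-phosphate transfer protein, was at least 11.9-fold higher by its called probe, which was not above background in wild-type, while its other probe changed by -0.14. Such a bound sets the brighter group's mean against the dimmer group's, with each dim array taken at no less than its lowest detected signal. Nicn1 (2.09), Thg1l (2.02), Il18 and Spag1 (1.73) had other probes at 0.25, 0.76, 0.06 and -0.34. Lhfpl3 rose by 1.80 (adjusted p = 0.0165), with other probes at 1.81 and 0.10. Its call was lost without wild-type replicate 2, knockout replicate 1 or knockout replicate 2, with a change of 1.47 to 2.13 over the arrays left out and an adjusted p up to 0.0762. Leaving out any 1 knockout array put the other Cptp probe in place of the called one, with changes of -0.30, -0.11 and -0.02 and adjusted p of 0.866, 0.964 and 0.986 without knockout replicates 1, 2 and 3. The largest increase of all, 6.62 (adjusted p = 7.48e-07), was that of a probe with no gene name here (ILMN_2540464), singled out after its value was seen.

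Among the 12 largest decreases, Ctsc, the cathepsin that activates granule serine proteases of immune cells, was not above background in knockout retina and was at least 23.9-fold lower (adjusted p = 7.83e-07). All 3 of its probes fell. Myo7a, the motor protein myosin VIIa of photoreceptors and pigment epithelium, was at least 18.4-fold lower (adjusted p = 1.47e-05), and Prrt4 at least 13.6-fold (adjusted p = 2.35e-06). The sulfate transporter Slc13a4 was at -4.07, the pentose phosphate enzyme Rpe at -3.84, Uap1, which makes UDP-N-acetylglucosamine, at -3.78, and Mns1 at -3.48. Sema5a, an axon guidance protein, was at -3.55, with another probe at -3.005 and a dim one at -0.01. For 4 of these decreases the other probes of the gene, which are much dimmer, moved less or the other way. Having less room to fall does not account for all of these. Tmem25 was at least 63.7-fold lower by its called probe, with other probes at -0.18 and 0.20. Epm2aip1, a laforin-binding protein, fell by 5.12, with its other probes between -0.45 and 0.39. Tomm22, a receptor of the mitochondrial import complex, was at -4.004 with another probe at -0.45, and Fgfr1op2 fell by 3.36 with another at 0.69. Of the 3 knockout arrays the called probes of Epm2aip1 and Fgfr1op2 were detected on 1, and those of Slc13a4 and Rpe on 2, so the size of these falls is limited by background. The Tmem25 call was lost without wild-type replicate 2 (0.25, adjusted p = 0.851), wild-type replicate 3 (0.49, adjusted p = 0.463) or wild-type replicate 1 (-0.14, adjusted p = 0.809), and the Fgfr1op2 call without wild-type replicate 2 (0.52, adjusted p = 0.533), in each case with another probe standing for the gene. Ctsc, Myo7a and Prrt4, seen on the 3 wild-type arrays alone, were not tested when one of those was left out.

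Photoreceptor genes moved in both directions. Pde6c, the catalytic subunit of the cone phosphodiesterase, fell from a log2 signal of 10.6 ± 0.291 (SD, n = 3) to 8.22 ± 0.153 (SD, n = 3), a change of -2.38 (SE 0.195, adjusted p = 0.000235), and its other probe fell by 2.08. Cone arrestin Arr3 rose by 0.91 (SE 0.153, adjusted p = 0.014), with its other probe higher by 1.42, and the cone transducin subunit Gnat2 rose by 0.95 (SE 0.196, adjusted p = 0.0397). The cone opsins did not pass: Opn1sw differed by 1.10 (SE 0.316, adjusted p = 0.156) and Opn1mw by -0.09 (adjusted p = 0.843). Of 16 tested cone markers 2 rose, 1 fell and 13 did not pass, and adjusted over the list alone 4 rose and 1 fell. The cone list as a whole had a median change of 0.12 (adjusted p = 0.281). Among rod genes the neighbouring guanylate cyclase activators went apart. Guca1b fell by 2.50 (SE 0.232, adjusted p = 0.000479), whereas Guca1a rose by 1.40 (SE 0.196, adjusted p = 0.00513; adjusted p = 0.0851 with the authors' table). Rgs9, which speeds the shut-off of transducin, rose by 1.38 (adjusted p = 0.0277), with its other probe at 0.22. Of 24 tested rod markers 2 rose, 1 fell and 21 did not pass, with the same numbers when adjusted over the list alone, and the list had a median of 0.02 (adjusted p = 0.638). The Arr3 call was lost without wild-type replicate 1, wild-type replicate 2, knockout replicate 1 or knockout replicate 2 (adjusted p up to 0.122, change 0.86 to 0.96), the Rgs9 call without wild-type replicate 1, wild-type replicate 2, knockout replicate 2 or knockout replicate 3 (up to 0.143, 1.19 to 1.66), and the Gnat2 call without any 1 of the 6 arrays (up to 0.165, 0.80 to 1.05).

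**Figure D3:**
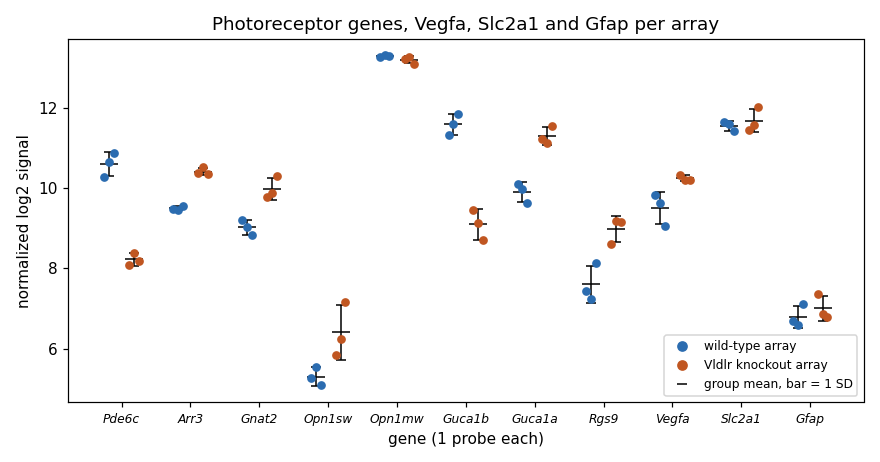
Normalized log2 signal (vertical axis) of 8 photoreceptor genes, Vegfa, Slc2a1 and Gfap (horizontal axis, 1 probe each) in the 3 wild-type and 3 knockout arrays; points are arrays, horizontal marks group means and bars 1 SD. Pde6c (-2.38) and Guca1b (-2.50) are lower and Arr3 (0.91), Guca1a (1.40) and Rgs9 (1.38) higher in every knockout array than in any wild-type array, whereas the groups overlap for Slc2a1 and Gfap.

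Glial genes did not move as a block. Apart from Serpina3n, 17 of the 18 tested reactive glia genes did not pass, among them Gfap, the filament protein of stressed Müller cells, at 0.21 (SE 0.22, adjusted p = 0.742), with a dimmer probe at -0.21. Adjusted over the list alone, 2 reactive glia genes rose. The list's median change was 0.14 (adjusted p = 0.252). Of 20 tested Müller glia markers 2 fell, 0 rose and 18 did not pass, and adjusted over the list alone 3 fell and 1 rose. Spc25, a kinetochore protein kept in the list as a marker, fell by 1.51 (SE 0.155, adjusted p = 0.000831; adjusted p = 0.0657 with the authors' table) and on its other probe by 0.95. Dapl1 fell by 1.01 (adjusted p = 0.0309), a call lost without any 1 array but wild-type replicate 3 (adjusted p up to 0.152, change -1.18 to -0.88). The Müller list had a median of 0.05 but a mean of -0.08, and its test pointed lower (adjusted p = 0.611). The probes of Rgr, a retinal G protein coupled receptor of Müller cells and pigment epithelium, disagreed: the one with the highest mean signal differed by 0.62 (adjusted p = 0.0802), another by 0.81 (adjusted p = 0.0439 over all probes) and the last by -1.84 (adjusted p = 0.000388 over all probes), so that 2 probes passed in opposite directions.

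As a list, markers of microglia and macrophages were lower in the knockout retinas, with 12 of the 17 tested lower and 5 higher in sign. Fcer1g, the Fc receptor gamma chain, was at least 5.74-fold lower (adjusted p = 0.000116), the lysozyme Lyz2, detected on 1 of 3 knockout arrays, fell by 0.90 (adjusted p = 0.0179) and the lipid receptor Trem2 fell by 0.75 (adjusted p = 0.0454). Of 17 tested markers 3 fell, 0 rose and 14 did not pass, and adjusted over the list alone 7 fell. The list had a median change of -0.34 and passed camera, limma's test of a list against all other genes (adjusted p = 0.00226), but not with the correlation between its genes estimated (adjusted p = 0.66 with an estimated correlation). The call was lost without wild-type replicate 1 (-0.24, adjusted p = 0.0913) and without wild-type replicate 2 (-0.15, adjusted p = 0.105). The median over the microglia list was 5.46 to 5.88 in wild-type arrays and 5.12 to 5.33 in knockout arrays. Lyz2 lost its call without any 1 array but wild-type replicate 3 (adjusted p up to 0.136, change -0.93 to -0.86) and Trem2 without any 1 of the 6 (up to 0.248, -0.83 to -0.69). Interferon response genes were also lower, with a median of -0.21 over 23 tested genes (adjusted p = 0.0201; adjusted p = 0.66 with an estimated correlation). Of these, the interferon-inducible GTPase Igtp fell by 0.99 (adjusted p = 0.0136), 22 did not pass, and 2 fell adjusted over the list alone. The antiviral gene Rsad2, detected on 1 of 3 knockout arrays, was at -0.72 (adjusted p = 0.0772). The interferon call was lost without wild-type replicate 1 (-0.17, adjusted p = 0.105) and knockout replicate 3 (-0.17, adjusted p = 0.0936), and Igtp lost its own without any 1 array but wild-type replicate 3 (adjusted p up to 0.0876, change -1.10 to -0.91). In the same arrays the erythrocyte list had a median of 0.68 and the ciliary body and iris list one of -0.20. Both passed camera, but not with an estimated correlation (adjusted p = 0.66 each), and 0 of 7 erythrocyte genes passed by limma.

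Endothelial markers were slightly higher, with a median change of 0.15 over 28 tested genes (adjusted p = 0.0241; adjusted p = 0.66 with an estimated correlation). Nos3, the endothelial nitric oxide synthase, rose by 0.98 (SE 0.172, adjusted p = 0.0178) and its other probes differed by 0.98 and 0.56. It was the only member called, and also the only one adjusted over the list alone, where 1 rose and 0 fell. Sox18, a vascular transcription factor, was at 0.92 (adjusted p = 0.134). Genes induced by hypoxia had a median of 0.14 over 27 tested genes (adjusted p = 0.0253; adjusted p = 0.66 with an estimated correlation), with 20 higher and 7 lower in sign. Over all genes 0 of the 27 passed by limma and adjusted over the list alone 1 rose. Vegfa, the main vessel growth factor of hypoxic retina, was higher by 0.73 (SE 0.216, adjusted p = 0.171), with its other probe at 0.39, the hypoxia-responsive repressor Bhlhe40 by 0.75 (adjusted p = 0.0536), and the glucose transporter Slc2a1 by 0.14 (SE 0.193, adjusted p = 0.817). The free fatty acid receptor Ffar1 was detected on 1 array and was not tested. The endothelial call was lost without wild-type replicate 1 (0.24, adjusted p = 0.0913), wild-type replicate 3 (0.08, adjusted p = 0.129) or knockout replicate 2 (0.15, adjusted p = 0.0777). The hypoxia call was lost without wild-type replicate 1 (0.17, adjusted p = 0.153), wild-type replicate 3 (0.11, adjusted p = 0.0602) or knockout replicate 3 (0.16, adjusted p = 0.156). Nos3 was called without wild-type replicate 2 or 3 but not without any other array (adjusted p up to 0.107, change 0.90 to 1.10). The erythrocyte list was higher by 0.68 in the same comparison, on the probe standing for each gene, but 0 of its 7 members passed by limma. Its camera call was lost with an estimated correlation (adjusted p = 0.66) and with every probe on its own (adjusted p = 0.837). Whether blood transcripts moved with these groups is therefore not settled.

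Wnt pathway genes were lower, with a median of -0.34 over 17 tested genes, 14 of them lower in sign (adjusted p = 0.00452; adjusted p = 0.582 with an estimated correlation). The secreted Wnt antagonist Sfrp1 fell by 0.91 (adjusted p = 0.0457), with its other probe at -0.45, and 16 members did not pass. Adjusted over the list alone 4 fell. Among the other members, Notum, a secreted deacylase that inactivates Wnt proteins, was not above background in knockout retina and was at least 2.06-fold lower (adjusted p = 0.0952), which did not pass. Sfrp1 and Notum are inhibitors of the pathway. The list's call was lost without wild-type replicate 3 (-0.18, adjusted p = 0.0602), and Sfrp1 lost its own without any 1 array but wild-type replicate 3 (adjusted p up to 0.223, change -1.06 to -0.79). Basement membrane and extracellular matrix genes had a median of -0.18 over 25 tested genes (adjusted p = 0.0241; adjusted p = 0.66 with an estimated correlation). Col18a1, the collagen that gives rise to endostatin, was at -1.596 (SE 0.16, adjusted p = 0.000729), with its other probe at -1.67. Loxl1, which cross-links elastin, fell by 0.87 (adjusted p = 0.0187). The other 23 did not pass, and adjusted over the list alone 3 fell. Without wild-type replicate 2 the matrix list was at -0.10 (adjusted p = 0.105) and without knockout replicate 3 at -0.15 (adjusted p = 0.0936), and Loxl1 lost its call without wild-type replicate 1, wild-type replicate 2, knockout replicate 1 or knockout replicate 2 (adjusted p up to 0.137, change -0.92 to -0.82).

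Genes of tissues next to the retina also differed. Such tissue can be carried over in dissection, and the list for ciliary body, iris and choroid was fixed for that reason. Whether the amount carried over differed between the groups was not tested. A list fixed for ciliary body, iris and choroid had a median of -0.20 over 12 tested genes (adjusted p = 0.00826; adjusted p = 0.66 with an estimated correlation). Of its members 3 fell, 0 rose and 9 did not pass, and adjusted over the list alone 4 fell and 1 rose. Optc, a vitreous proteoglycan made by the ciliary body and detected on 2 of 3 knockout arrays, fell by 2.93 (SE 0.149, adjusted p = 1.47e-05), the matrix proteoglycan Ogn fell by 1.91 (adjusted p = 0.0011) and the transcription factor Zic1 fell by 1.25 (adjusted p = 0.0106). The list's call was lost without wild-type replicate 1 (-0.23, adjusted p = 0.0913), and that of Zic1 without wild-type replicate 1, wild-type replicate 2 or knockout replicate 1 (adjusted p up to 0.0624, change -1.36 to -1.10). Erythrocyte genes were higher on the probe standing for each gene, with a median of 0.68 over 7 members (adjusted p = 0.0185; adjusted p = 0.66 with an estimated correlation), although 0 of them passed by limma and 1 rose adjusted over the list alone. Without wild-type replicates 1 and 2 in turn the erythrocyte adjusted p was 0.105 and 0.118 (medians 0.64 and 0.34), and without knockout replicates 1, 2 and 3 it was 0.615, 0.274 and 0.156 (medians 0.29, 0.63 and 0.85). The probes of the beta globin genes went both ways, from -3.95 to 1.33 for Hbb-bs and down to -1.32 for Hbb-bt. By limma over all tested probes, the Hbb-bs probe at -3.95 (adjusted p = 0.000264) and an Hbb-bt probe at -0.90 (adjusted p = 0.0355) passed, both lower. The Hbb-bs probe at 1.33 did not (adjusted p = 0.239). Lens genes had a median of 0.84 (adjusted p = 0.0767) with 0 of 19 members past the threshold, over all genes or adjusted over the list alone, and Cryaa, a lens chaperone detected on 2 of 3 wild-type arrays, at 1.41 (SE 0.838, adjusted p = 0.535). The lens list passed without wild-type replicate 3 (1.33, adjusted p = 0.0272), knockout replicate 2 (1.63, adjusted p = 0.000113) or knockout replicate 3 (1.37, adjusted p = 0.00629), and was at -0.27 (adjusted p = 0.213) without knockout replicate 1. Of 20 tested pigment epithelium and melanocyte markers, Bmp4, a growth factor, fell by 2.93 (SE 0.171, adjusted p = 2.81e-05) and 19 did not pass. Adjusted over the list alone 1 fell (list median -0.07, adjusted p = 0.332). The median level over this list was 6.867 to 7.21 in wild-type and 6.095 to 6.435 in knockout arrays, with 12 members lower and 8 higher in sign.

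**Figure D4:**
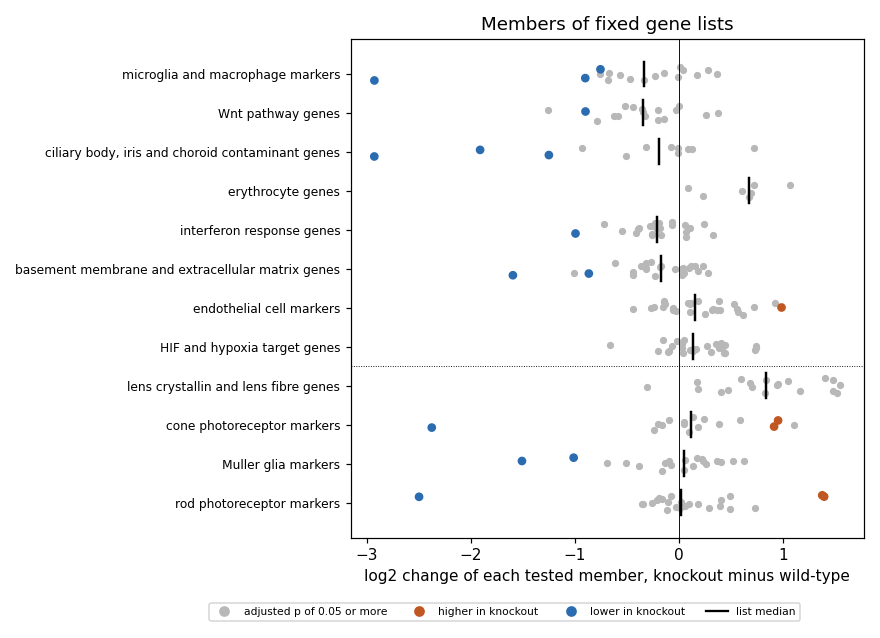
Log2 change between knockout and wild-type retina (horizontal axis) of each tested member of 12 fixed gene lists (vertical axis); black bars are list medians and coloured points are members past an adjusted p of 0.05. The 8 lists above the dotted line passed camera with a preset correlation, with medians from -0.34 in microglia and Wnt genes to 0.68 in erythrocyte genes; lens, cone, rod and Müller lists did not.

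In all, 8 of 34 lists passed camera with a preset correlation, 5 lower and 3 higher in knockout, and with an estimated correlation 0 did. The rotation test fry asks whether a list's genes move, on balance, one way, without comparing them with other genes. It called 2 lists, Wnt (adjusted p = 0.0267) and ciliary body, iris and choroid (adjusted p = 0.0284). Over 21 alternatives the adjusted p of the 8 lists ran from 4.76e-05 to 0.66 for microglia, 0.00263 to 0.582 for Wnt, 0.00119 to 0.66 for ciliary body, 0.000458 to 0.837 for erythrocyte, 0.00518 to 0.66 for both interferon and matrix, 0.00557 to 0.66 for endothelial and 0.000493 to 0.66 for hypoxia genes.

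Genes of energy and lipid metabolism changed singly. Pkm, the pyruvate kinase of the last step of glycolysis, fell by 1.53 (SE 0.206, adjusted p = 0.00389; adjusted p = 0.0903 with the authors' table), as 1 of 22 tested glycolysis genes to pass, over all genes and adjusted over the list alone (list median 0.12, adjusted p = 0.466). The malic enzyme Me1 was at least 3.74-fold lower (adjusted p = 0.000282) and the cystine transporter Slc7a11 fell by 1.08 (adjusted p = 0.02), with its other probe at -0.03. These were the 2 of 22 antioxidant genes that passed, also adjusted over the list alone, with a list median of 0.05, a mean of -0.08 and a test that pointed lower (adjusted p = 0.921). Among 22 tested cholesterol synthesis genes the sterol carrier Stard4 rose by 1.26 (SE 0.241, adjusted p = 0.0288), and adjusted over the list alone 1 rose and 1 fell (list median -0.10, adjusted p = 0.921). Of 17 reelin and lipoprotein receptor genes Vldlr was the only one past the threshold, over all genes and adjusted over the list alone (list median -0.11, adjusted p = 0.638). Lrp8, the related reelin receptor, differed by 0.05 (SE 0.212, adjusted p = 0.949) and Reln by -0.34 (adjusted p = 0.471). Of 28 fatty acid oxidation genes 0 passed by limma and 1 fell adjusted over the list alone (median 0.03, adjusted p = 0.921), and of 32 respiratory chain genes 0 passed either way (median 0.06, adjusted p = 0.428). The Stard4 call was lost without wild-type replicate 1, wild-type replicate 2, knockout replicate 2 or knockout replicate 3 (adjusted p up to 0.154, change 1.01 to 1.44), and so was that of Slc7a11 (up to 0.12, -1.21 to -0.89).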

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

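Leaving out knockout replicate 1 and wild-type replicate 3 together was chosen after the data were seen, and all other alternatives before. No alternative turned the direction of Vldlr or of a called list. Of 53 named genes called besides Vldlr, 26 passed under every alternative in which they could be tested, among them Serpina3n, Gdpd3, Il18, Ctsc, Myo7a, Sema5a, Bmp4, Optc, Pde6c and Guca1b, and 3 changed direction under some. Of 104 named genes without a call, 46 passed under at least 1 alternative. The count of 350 was within 1.5 times itself under the alternatives not mentioned below, and 347 without genes within 10 Mb of Vldlr. The files name no slide, so a slide block was not run. Changes of dim probes are limited by their signal over background. Except where a reason is given, the cause was not tested.

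With the authors' table and with the value table of the series, which hold the same values, 170 genes were called, 48 higher and 122 lower, 152 of them shared with the 350. Vldlr was at -1.15 (adjusted p = 0.112, against 0.000455 to 0.223 over its alternatives), the matrix list at -0.176 and the erythrocyte list at 0.675, all without a call. With no filter on dim probes 62 genes were higher, and the interferon (-0.0666) and Wnt (-0.0711) lists lost their calls, with 29453 features tested. With the strict filter 4 lists passed, and the endothelial (0.113), erythrocyte (0.676), hypoxia (0.135) and interferon (-0.217) lists did not. With the mean of a gene's probes Vldlr was at -0.683 (adjusted p = 0.223), since its dim probes enter the mean, and the erythrocyte list at 0.233, which lost its call, while the bipolar list passed (0.241). With every probe on its own the erythrocyte list was at 0.61 and lost its call (adjusted p = 0.837), while the bipolar (0.19) and proliferation (-0.151) lists passed. With array weights 960 genes were called, 421 higher (43.9% against 30.3%) and 539 lower, with all 350 among them, but 5 lists, without matrix (-0.166), hypoxia (0.115) and interferon (-0.173) genes. At an adjusted p of 0.10, 166 genes were higher. Without the 2 arrays that stand apart 207 genes were called, 50 higher and 157 lower, with 169 shared. Vldlr was then at -1.003 (adjusted p = 0.0556) and 5 lists passed, without the endothelial (0.0486), erythrocyte (0.697) and Wnt (-0.24) lists.

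With an estimated correlation 0 lists passed, at unchanged medians of -0.335 (microglia), -0.341 (Wnt), -0.196 (ciliary body), 0.676 (erythrocyte), -0.207 (interferon), -0.177 (matrix), 0.15 (endothelial) and 0.135 (hypoxia). With fry 2 passed and the other 6 of these did not.

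The titles share the numbers 4 and 5 between groups. The deviations of same-numbered arrays correlated at -0.0379 and -0.22, which gives no sign that the numbers pair the samples. Deviations within a group sum to 0 for each probe, so such correlations are tied to each other and cannot settle the pairing. Arrays in the same place of the sample order deviated together (0.286, 0.28 and 0.323, against -0.253 to 0.0483 for the others), a hint from the data and not the design, and no block was fitted on it because that order only names the samples. With the title number as a replicate block 293 genes were called, 241 shared, Vldlr was at -1.005 (adjusted p = 0.063) and the endothelial list at 0.0495, both without a call, and the cone, rod and proliferation lists passed. Wild-type replicate 3 and knockout replicate 1 share their number with no other array, so they added nothing to the group difference in that fit. It rested on the same arrays as leaving those 2 out together (Vldlr at -1.003), so these alternatives are not separate checks.

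Leaving out 1 array at a time gave 156 to 324 genes, 29 to 108 higher and 110 to 216 lower, and 2 to 7 lists. Vldlr ran from -1.26 to -1.06. List medians ran from -0.536 to -0.152 (microglia), -0.488 to -0.182 (Wnt), -0.285 to -0.189 (ciliary body, with -0.511 under the strict filter and -0.0808 under no filter, still called), 0.291 to 0.984 (erythrocyte), -0.28 to -0.156 (interferon), -0.305 to -0.0993 (matrix), 0.0784 to 0.243 (endothelial) and 0.111 to 0.211 (hypoxia). Without a wild-type array 55 of the 350 could not be tested, and without a knockout array 7, since their probes were then detected on too few arrays.

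The 3 genes that changed direction did so because another probe stood for them. Tmem25 was at 0.253 without wild-type replicate 2, 0.492 without wild-type replicate 3 and 0.624 without the 2 arrays that stand apart. Cptp was at -0.297, -0.111 and -0.0204 without knockout replicates 1, 2 and 3 and at -0.536 without the 2 arrays. Fgfr1op2 was at 0.52 without wild-type replicate 2, where the called probe was still tested but no longer the brightest, and at 0.851 without the 2 arrays. In all other cases the called probe no longer passed the detection filter. The called probes of Tmem25 and Cptp are below background in 1 group, so that with all 6 arrays only bounds hold (at least 63.7-fold lower and 11.9-fold higher) and the ends given here are fitted values, not measured sizes. Over the 6 arrays left out in turn Tmem25 ran from -6.414 to 0.492, Cptp from -0.297 to 4.116 and Fgfr1op2 from -3.465 to 0.52.

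Calls of named genes besides Vldlr were also lost, in the same direction, under settings other than leaving out 1 array. The authors' table and the value table of the series lost Arr3, Col18a1, Ebf1, Fos, Gnat2, Guca1a, Igtp, Lhfpl3, Loxl1, Mcm2, Nos3, Pkm, Rgs9, Sfrp1, Spc25, Stard4 and Zic1. Quantile normalization of raw signal lost Dapl1, Ebf1, Lyz2, Mcm2, Sfrp1, Slc7a11, Stard4 and Trem2, and median scaling lost Ebf1, Fos, Gnat2, Loxl1, Mcm2, Nos3, Rgs9, Sfrp1, Stard4 and Trem2. An offset of 50 lost Ebf1, Lyz2, Mcm2, Sfrp1 and Trem2, and a trended and robust variance Ebf1, Mcm2, Sfrp1 and Trem2. No filter lost Cd59a, Dapl1, Ebf1, Fos, Gnat2, Lhfpl3, Rgs9, Sfrp1, Slc7a11 and Stard4. The mean of probes lost Ebf1, Sfrp1, Slc7a11, Spag1 and Vip, and every probe on its own Ebf1, Sfrp1 and Trem2. The title number as a block (293 genes called) lost Arr3, Cd59a, Ebf1, Gnat2, Loxl1, Lyz2, Mcm2, Nos3, Trem2 and Vip, and the 2 arrays left out lost the same genes but Vip, and Lhfpl3. In both settings the group difference rests on the same arrays.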

Other observations

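The tests of brighter probes, of shared regulation and of lens transcripts, the count of splits at an unadjusted p and the choice of the neighbouring genes named here were made after the results were seen. The other tests were set beforehand.

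Neurons of the inner retina changed singly. Vip, a peptide of amacrine cells, rose by 1.26 (SE 0.191, adjusted p = 0.00787), with a dim second probe at -0.07, as the only 1 of 19 amacrine markers past the threshold (list median 0.06, adjusted p = 0.808; adjusted over the list alone 1 rose and 1 fell). Npy was at -0.80 (adjusted p = 0.0593). Ebf1, a transcription factor in the ganglion cell list, fell by 0.99 (adjusted p = 0.0432), with another probe at 0.20, as the only 1 of 15 ganglion cell markers, also adjusted over the list alone (list median 0.08, adjusted p = 0.903). Of 18 bipolar markers 0 passed by limma (median 0.19, adjusted p = 0.178) and of 5 horizontal cell markers 0 passed (median -0.11, adjusted p = 0.749), with 0 adjusted over either list alone. Mural cell markers had 0 of 12 past the threshold, either way, with Rgs5 at 2.15 (SE 0.578, adjusted p = 0.126; list median 0.01, adjusted p = 0.658). Without wild-type replicate 2 the Vip adjusted p was 0.052. Ebf1 lost its call without any 1 array but wild-type replicate 3 (adjusted p up to 0.193, change -1.10 to -0.79).

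Among stress and immune genes, the immediate early gene Fos rose by 1.24 (SE 0.214, adjusted p = 0.0165), 1 of 21 in its list, with 3 adjusted over the list alone (list median 0.01, adjusted p = 0.238), and Egr1 was at 1.10 (adjusted p = 0.132). Cd59a, which blocks the complement attack complex, rose by 1.08 (SE 0.19, adjusted p = 0.0178), 1 of 12 complement genes, while C1qb was at -0.68 (adjusted p = 0.149). The complement list had a median of 0.01, a test that pointed lower (adjusted p = 0.921), and 1 rise and 1 fall adjusted over the list alone. Il18 was the only 1 of 12 cytokine and chemokine genes past the threshold, with 1 rise and 1 fall adjusted over the list alone (median 0.08, adjusted p = 0.281). The replication factor Mcm2 fell by 0.85 (adjusted p = 0.0307), 1 of 14 proliferation genes, also adjusted over the list alone (median -0.09, adjusted p = 0.178). Cell death and unfolded protein genes had 0 of 21 past the threshold either way (median -0.07, adjusted p = 0.332). Of 39 angiogenesis regulators Col18a1 alone passed, with 1 rise and 1 fall adjusted over the list alone (median -0.04, adjusted p = 0.98). Ribosomal protein genes (0 of 27, median 0.03, adjusted p = 0.921, 1 fall adjusted over the list alone) and clock genes (0 of 16, median -0.05 with a test that pointed higher, adjusted p = 0.921, 1 rise and 1 fall adjusted over the list alone) did not pass. Cd59a lost its call without wild-type replicate 2, knockout replicate 1 or knockout replicate 2 (adjusted p up to 0.116, change 0.95 to 1.20), Fos without wild-type replicates 1 or 2 or knockout replicates 2 or 3 (up to 0.1, 1.12 to 1.41), and Mcm2 without any 1 array but wild-type replicate 3 (up to 0.166, -0.92 to -0.76).

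Called genes lay next to each other in chromosome order in 21 pairs, among them Ctsc (at least 23.9-fold lower) and Rab38 (-1.52), Apoa2 and Fcer1g (at least 3.37-fold and 5.74-fold lower), Zic1 (-1.25) and Zic4 (at least 2.04-fold lower), and Guca1b (-2.50) and Guca1a (1.40). Strain alleles flanking the targeted gene on chromosome 19 were tested first, and called genes were no denser there: 2 of 74 tested genes within 10 Mb of Vldlr were called (2.7%) against 277 of 10992 elsewhere (2.52%, odds ratio 1.07, Fisher's exact test, one-sided p = 0.56), and the fixed list of flanking genes had 0 of 37 past the threshold, also adjusted over the list alone (median 0.03, mean -0.02, test lower, adjusted p = 0.903). The 21 pairs exceeded all of 10000 random placements of the calls (median 7, highest 19, permutation p = 1e-04, the smallest they can give), so strain-derived segments elsewhere in the genome may account for part of the calls. Shared regulation of neighbours may do so too, as only 3 of the pairs went in opposite directions, against a median of 9 and a 5th percentile of 5 when directions were shuffled. Both stay open, as does an effect of the knockout itself, which was not tested apart from them. The 2 calls among 74 genes near Vldlr are too few to exclude a moderate excess there.

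Among the 228 named genes called at a fitted 2-fold or more, 88 had another detected probe. Of these, 38 had another probe that followed (ratio of changes 0.5 or more, p under 0.05) and 39 had all other probes under 0.25. Sequence or isoform differences under single probes were tested on these 88: the other probe's change was a median of 0.233 of the called probe's over 120 probes, which met the bound of under 0.25 set beforehand for such differences. Among the 49 other probes with a mean log2 of 6 or more the median was 0.633. Of these probes 25 were at 0.5 or more and 21 under 0.25. That cut was chosen after the first median was seen, some genes give several of these probes, and Vldlr is among them. The medians therefore do not decide the question for these genes as a set. Where another probe followed, the change does not rest on 1 probe alone. In 18 genes a bright other probe stayed under 0.25, and there, as for rises such as Cptp, Il18 and Vip, whose dim other probes (-0.14, 0.06 and -0.07) had room to rise, a sequence or isoform difference may still account for the call. For falls with a dim other probe that did not rise, this and a change of the whole transcript could not be told apart. The same holds for the rises of Cptp, Il18 and Vip, since a probe that dim may not follow its transcript. A probe near background has little room to fall, which does not account for a rise such as that of Fgfr1op2 (0.69).

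Lens transcripts were high in knockout replicate 1, where all 19 tested lens genes had their highest value and exceeded the mean of the other 5 arrays by a median of 3.52 on the log2 scale. Lens tissue carried over in dissection may account for the excess, as a hypothesis from the same values. A difference in lens gene expression within the retina of that sample was not tested.

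The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 350 genes and the highest other split 0, and as many as 350 came from 1 of the 10. At an unadjusted p under 0.05 limma gave 1733 features in the real split and at most 1329 in another. Every other split has arrays of both groups on each side, so a group difference widens its spread and its count is not one of chance alone.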
